A study of Mus musculus with 15 samples.

How the data were processed

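The deposited files held gene counts, made by the authors for each library. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned to mm10 with STAR, and counted per gene by STAR. Versions of Trimmomatic and STAR, and the gene annotation release, are not given in the sources used here. Per the labels, RNA came from fresh frozen liver of male FVB/NJ mice and was isolated with the RNeasy Mini kit, and libraries followed standard Illumina protocols. The 15 libraries formed 5 groups of 3, with the mutations S45Y and G31A named in the labels. The labels give no age, day of harvest, vector, time after transgene delivery or pairing. Replicate numbers used here follow the order of the samples. No paired analysis was possible because the labels give no replicate numbers that link samples across groups.

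Each file held an unstranded count column and a column for each strand. Column 3 held 49.7 to 49.9% of the sum of both strand columns, so by the rule set before the data were examined the unstranded column was used. Genes that overlap on opposite strands are therefore uncertain, and so are near-identical gene copies such as the Cyp2a, Cyp2b, Cyp2c, Cyp2d, Cyp3a, Cyp4a12, Sult, Mup, Saa, Gsta and H2 families. The files listed 24411 gene symbols, and 14098 genes passed filterByExpr by group. Gene counts summed to between 14084343 (WT replicate 1) and 20702618 (CTNNB1_MET replicate 3) in each library. Group means of the special counts were 10.3 to 22.9% unmapped, 5.27 to 6.10% multimapping, 7.41 to 9.34% without a gene and 1.53 to 1.93% ambiguous. The 15 pairs of replicates were compared gene by gene for duplicates, and the chi-square per gene was 14.1 to 116. NFE2L2_MET replicate 1 had 1.32% of its counts in the ribosomal RNA gene Rn45s. Gene coordinates are from the GRCm38.p6 annotation, which is the mm10 assembly.

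The design, the gene lists, the 8 contrasts, the named-gene rule and most alternative settings were chosen before the data were examined. Testing used R 4.3.3 with edgeR 4.0.16. TMM-normalised counts were fitted with 1 coefficient per group over all 15 libraries and tested with the edgeR quasi-likelihood F test (robust), with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of the log2 fold changes come from the F statistic of the same fit. The 32 lists held 470 genes, of which 468 are in the files. They were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, adjusted over all 256 tests, and again with an estimated correlation and with fry. Camera called 134 of 256 tests, the estimated correlation 1 and fry 156. Genes named in the text are the introduced genes, the 6 largest rises and falls with a mean log2 CPM of at least 3, 4 members of each list with the smallest p, and a set of well-known members. Car4, Rian, Meg3, Mirg and Nxpe2 are also named as members of the set higher in all 6 contrasts. Some genes that met the rule are not reported here, and the counts of named genes under other settings leave them out.

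The test step was tried on counts simulated from the real libraries with known changes in the contrast of CTNNB1 added, over 13882 genes. It called 67 of 99 genes changed 2-fold and 92 of 99 changed 4-fold, all with the right sign. It called 9 of 14 further genes changed 2-fold as members of a shifted list, and 5 of 13670 unchanged genes, and 2.89% of its calls were false. DESeq2 1.42.0 called 70, 93, 9 and 14 in the same sets. A simulated shift of the β-catenin target list gave a camera adjusted p of 2.65e-21 and an adjusted p of 0.00173 with an estimated correlation, and 0 of 96 list tests without change were called. The simulated genes were drawn independently of each other. The simulation therefore does not show how correlation between genes affects the list calls in the real data.

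The settings chosen in advance were RLE size factors, no low-count filter, a single-strand count column, DESeq2, only the libraries of a contrast, a term for the 3 libraries marked as added in their file labels, the fit without these 3, and leaving out each library. Total-count scaling, a term for the unmapped share and list tests with each library left out were added after the data were seen. Where leaving out 1 library ended a list call, the highest such p is printed beside it. The 3 marked libraries were WT replicate 3, CTNNB1_NFE2L2_MET replicate 3 and CTNNB1_MET replicate 3. TMM and RLE left the all-gene median within 0.04 of 0 in each contrast.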

Results

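Male FVB/NJ liver was profiled by polyA RNA sequencing in 5 groups of 3 libraries each. WT was wild-type liver, and the other groups carried combinations of a mutant β-catenin (S45Y), a mutant NRF2 (G31A, encoded by NFE2L2) and human MET. The S45 residue belongs to the phosphorylation sites that mark β-catenin for degradation, G31 lies in the NRF2 motif bound by KEAP1, and MET is the receptor of hepatocyte growth factor. The groups are named here by their transgenes as CTNNB1_NFE2L2_MET, CTNNB1_MET, CTNNB1_NFE2L2 and NFE2L2_MET. Each transgene can therefore be read as added to a background that holds the other pair, and each model can be read against WT. Among 14098 tested genes, 4325 changed when CTNNB1 was added to NFE2L2_MET, 4765 when NFE2L2 was added to CTNNB1_MET and 3520 when MET was added to CTNNB1_NFE2L2. Against WT, 7039 genes changed in CTNNB1_NFE2L2_MET, 2429 in CTNNB1_MET, 6867 in CTNNB1_NFE2L2 and 3303 in NFE2L2_MET. The first 3 principal components carried 43.0%, 18.1% and 12.9% of the variance. Nothing in the labels says that the samples came from separate animals, so the p-values measure the spread between these samples. Gene values are log2 fold changes ± standard error, and group levels are mean CPM (counts scaled to TMM-adjusted totals) ± standard deviation with n = 3.

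**Figure D1:**
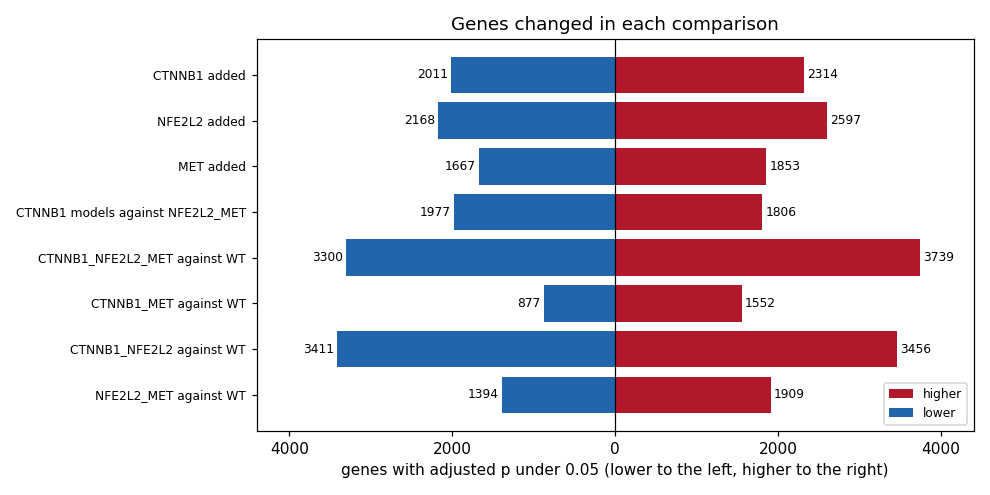
Numbers of genes called higher and lower (edgeR, adjusted p below 0.05) in each of the 8 contrasts between groups of 3 libraries, 1 bar for each direction. CTNNB1_NFE2L2_MET against WT had the largest total, 3739 higher and 3300 lower, and CTNNB1_MET against WT the smallest, 1552 higher and 877 lower.

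The mouse genes that correspond to the transgenes gave a limited view of the introduced sequences. Reads of human MET align to the mouse gene only in part, and counts do not separate transgene from endogenous reads. Only MET is labelled human. Ctnnb1 rose in CTNNB1_NFE2L2_MET against WT (0.72 ± 0.11), from 266 ± 26.3 to 439 ± 25.6 CPM. It also rose in CTNNB1_NFE2L2 against WT (0.46 ± 0.11). In CTNNB1_MET against WT it passed narrowly (0.35 ± 0.11, adjusted p = 0.0455, 0.29 without WT replicate 1), and likewise in NFE2L2_MET, which carries no CTNNB1 transgene (0.33 ± 0.11, adjusted p = 0.0483, 0.27 without WT replicate 1). Both calls were lost without WT replicate 1. The averages were 366 ± 19.4 CPM in CTNNB1_NFE2L2, 339 ± 42.0 in CTNNB1_MET and 334 ± 19.5 in NFE2L2_MET. Nfe2l2 and Met passed the test in none of the 8 contrasts. Met stood at 75.9 ± 21.3 CPM in WT and at 70.0 ± 4.45 CPM in CTNNB1_MET.

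For CTNNB1 added, CTNNB1_NFE2L2_MET was set against NFE2L2_MET. β-catenin is the effector of Wnt signalling and in normal liver sets the gene programme of hepatocytes next to the central vein. Hepatocytes next to the portal vein run the opposite programme of urea synthesis, amino acid breakdown and gluconeogenesis. The contrast moved 2314 genes up and 2011 down, of which 1687 changed 2-fold or more in either direction. Total-count scaling, in which the all-gene median stood at log2 0.38 instead of near 0, gave 6133 higher and 795 lower.

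Direct targets of β-catenin rose. Of 15 measured members 13 rose, 1 fell and 1 did not pass, or 13 and 1 adjusted over the list alone (camera adjusted p = 1.72e-11 and adjusted p = 0.228 with an estimated correlation). Nkd1, a feedback inhibitor of Wnt signalling, rose 38.0-fold (5.25 ± 0.25), and Sp5, a transcription factor switched on by β-catenin, rose 26.0-fold (4.70 ± 0.27). Axin2, a scaffold of the destruction complex (3.48 ± 0.25), Lgr5, a receptor for R-spondins (3.65 ± 0.28), and Notum, a secreted enzyme that inactivates Wnt ligands (1.94 ± 0.13), rose as well. Of 17 pericentral hepatocyte genes, 11 rose, 1 fell and 5 did not pass, or 11 and 2 adjusted over the list alone (camera adjusted p = 1.14e-05 and adjusted p = 0.231 with an estimated correlation). Glul, the glutamine synthetase of the pericentral layer (chromosome 1, 153899929 to 153909723), rose 9.10-fold (3.19 ± 0.16), from 313 ± 45.4 to 2850 ± 288 CPM. The ammonium transporter Rhbg (4.25 ± 0.23), the hepatokine Lect2 (3.31 ± 0.20) and the aryl hydrocarbon receptor Ahr (2.29 ± 0.16) also rose, while Cyp2e1 did not pass (0.16 ± 0.23, adjusted p = 0.649). Periportal genes moved down, and of 17 members 15 fell, 0 rose and 2 did not pass, or 15 and 0 adjusted over the list alone (camera adjusted p = 2.69e-10 and adjusted p = 0.231 with an estimated correlation). Cyp2f2, a periportal cytochrome P450 (chromosome 7, 27119955 to 27133660), fell (-3.46 ± 0.48). The mitochondrial aldehyde dehydrogenase Aldh1b1 (-3.17 ± 0.18), the urocanase Uroc1 (-2.51 ± 0.24), the arginase Arg1 (-2.48 ± 0.23) and the lipid-droplet protein Hsd17b13 (-1.69 ± 0.12) fell with it. Among the largest changes, the cadherin Cdh17 rose 92.1-fold (6.53 ± 0.41). The imprinted non-coding RNAs Rian (4.75 ± 0.32) and Meg3 (4.49 ± 0.36) and the poorly characterised Nxpe2 (4.63 ± 0.24) also rose strongly. Large losses included the trefoil peptide Tff3 (-4.99 ± 0.31), the protease inhibitor Spink1 (-4.43 ± 0.32), the sugar transporter Slc45a1 (-3.78 ± 0.30) and the growth factor Nrg4 (-3.65 ± 0.32).

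Several lists of hepatocyte transcripts were lower in the same contrast, while fatty acid oxidation was not called and glycolysis was higher. Secretory and metabolic genes are the products by which a differentiated hepatocyte is recognised, and of 20 members 13 fell, 0 rose and 7 did not pass, or 17 and 0 adjusted over the list alone (camera adjusted p = 7.6e-09 and adjusted p = 0.231 with an estimated correlation). Coagulation factor genes F9 (-1.35 ± 0.15) and F2 (-0.85 ± 0.13) and the apolipoprotein genes Apoc3 (-1.30 ± 0.17) and Apoa1 (-1.13 ± 0.17) fell. Of 7 urea cycle genes, whose products turn ammonia into urea, 5 fell, 0 rose and 2 did not pass, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.00104 and adjusted p = 0.276 with an estimated correlation). Asl (-1.28 ± 0.21), Otc (-1.88 ± 0.30) and Cps1 (-1.93 ± 0.37) were among them. A further member, Ass1, had too few counts to be tested in any contrast. Of 14 genes of bile acid synthesis and transport, 8 fell, 1 rose and 5 did not pass, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.011 and adjusted p = 0.398 with an estimated correlation). The uptake carrier Slc10a1 (-1.56 ± 0.22) and the bile acid receptor Nr1h4 (-1.05 ± 0.20) were among them. Of 14 fatty acid synthesis genes 10 fell, 1 rose and 3 did not pass, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.000142 and adjusted p = 0.26 with an estimated correlation). Examples were the citrate lyase Acly (-1.31 ± 0.14), the carboxylase Acaca (-1.01 ± 0.13) and the synthase Fasn (-1.29 ± 0.25). Cholesterol synthesis genes included 4 that fell, 0 that rose and 10 that did not pass, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.0148 and adjusted p = 0.589 with an estimated correlation, 0.0875 without NFE2L2_MET replicate 1). The reductase Dhcr7 (-1.61 ± 0.25) led this list. Of 15 fatty acid oxidation genes, 3 rose, 5 fell and 7 did not pass, or 3 and 7 adjusted over the list alone (camera adjusted p = 0.204), and the list median of -0.28 and mean of 0.01 differed in sign. Pdk4, a kinase that spares glucose, rose (2.86 ± 0.47). Of 12 glycolysis genes, 5 rose, 0 fell and 7 did not pass, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.0336 and adjusted p = 0.493 with an estimated correlation, 0.175 without CTNNB1_NFE2L2_MET replicate 1). The pyruvate kinase Pkm (2.10 ± 0.27) and the glucose transporter Slc2a1 (1.52 ± 0.23) were higher.

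Cell cycle transcripts rose. Of 24 cell cycle genes 23 rose, 0 fell and 1 did not pass, or 23 and 0 adjusted over the list alone (camera adjusted p = 2.6e-17 and adjusted p = 0.231 with an estimated correlation). Mki67, the standard proliferation marker, rose 10.8-fold (3.44 ± 0.22), and the mitotic kinases Cdk1 (2.90 ± 0.21) and Plk1 (3.06 ± 0.24) and the topoisomerase Top2a (2.63 ± 0.20) rose as well. NRF2 targets increased further although both groups carried G31A-NFE2L2, and of 35 members 19 rose, 1 fell and 15 did not pass, or 23 and 1 adjusted over the list alone (camera adjusted p = 3.07e-07 and adjusted p = 0.31 with an estimated correlation). The quinone reductase Nqo1 (1.41 ± 0.16), the glutathione reductase Gsr (1.39 ± 0.16) and the sulfiredoxin Srxn1 (1.36 ± 0.21) were among them. Of 15 oncofetal and tumour marker genes, 7 rose, 2 fell and 6 did not pass, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0366 and adjusted p = 0.42 with an estimated correlation, 0.0753 without NFE2L2_MET replicate 2). The stem-cell marker Prom1 (3.84 ± 0.26), the guidance receptor Robo1 (2.58 ± 0.27), the fetal albumin homologue Afp (2.48 ± 0.47) and the cell-surface glypican Gpc3 (2.15 ± 0.40) rose. ERK pathway output genes, transcribed downstream of receptor tyrosine kinases such as MET, were not called as a group. Of 15 members, 4 rose, 0 fell and 11 did not pass, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.06), with the ETS factor Etv5 (1.43 ± 0.19) the most certain.

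Immune transcripts were partly higher in this contrast. T and NK cell markers report the amount of lymphocyte RNA in the tissue, and of 12 members 7 rose, 0 fell and 5 did not pass, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.00621 and adjusted p = 0.31 with an estimated correlation). The interleukin-2 receptor chain Il2rb (1.63 ± 0.32), the granzyme Gzma (2.27 ± 0.46) and the activating receptor Klrk1 (1.67 ± 0.38) rose, while the chemokine Ccl5 did not pass (0.86 ± 0.40, adjusted p = 0.115). Cd8a had too few counts to be tested. Of 7 B and plasma cell markers, 3 rose, 0 fell and 4 did not pass, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.0802), with the receptor chain Cd79b higher (1.85 ± 0.36). Interferon response genes included 11 that rose, 1 that fell and 8 that did not pass, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.00326 and adjusted p = 0.391 with an estimated correlation). The deconjugating protease Usp18 (2.22 ± 0.24) and the GTPase Gbp2 (1.55 ± 0.22) were among them. Of 16 antigen presentation genes, 8 rose, 0 fell and 8 did not pass, or 10 and 0 adjusted over the list alone (camera adjusted p = 0.012 and adjusted p = 0.459 with an estimated correlation). The peptide-exchange chain H2-DMa (1.02 ± 0.20) and the class II activator Ciita (1.20 ± 0.30) were examples. Of 7 checkpoint genes, which restrain T cells, 3 rose, 0 fell and 4 did not pass, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.0321 and adjusted p = 0.26 with an estimated correlation, 0.097 without CTNNB1_NFE2L2_MET replicate 1). Cd274, which encodes PD-L1, rose (1.32 ± 0.33), as did Cd276, which encodes B7-H3 (1.46 ± 0.22). Of 10 chemokine genes, 1 rose, 1 fell and 8 did not pass, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.184). The neutrophil attractant Cxcl1 fell (-2.64 ± 0.63). Of 12 acute phase genes, 3 fell, 0 rose and 9 did not pass, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.0122 and adjusted p = 0.549 with an estimated correlation). The orosomucoid Orm1 was an example (-2.11 ± 0.50). NFE2L2_MET replicate 2 stood apart in acute phase genes, with Saa1 at 5915 CPM against 936 and 872 CPM in replicates 1 and 3. Without it 2 acute phase genes fell and 10 did not pass, or 2 adjusted over the list alone (camera adjusted p = 0.0495 and adjusted p = 0.635 with an estimated correlation).

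Other cell type markers followed. Of 17 macrophage and Kupffer cell markers, 7 rose, 1 fell and 9 did not pass, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.113), with the complement component C1qb slightly higher (0.64 ± 0.15). Of 9 dendritic cell markers, 3 rose, 0 fell and 6 did not pass, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.0692). The transcription factors Irf8 (0.76 ± 0.17) and Batf3 (1.68 ± 0.41) were among them. Of 3 neutrophil markers 1 fell, 0 rose and 2 did not pass, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.107). Of 15 endothelial markers, 6 fell, 0 rose and 9 did not pass, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.0366 and adjusted p = 0.484 with an estimated correlation, 0.0885 without CTNNB1_NFE2L2_MET replicate 3). The sinusoidal lectin Clec4g (-1.02 ± 0.23) and the Fc receptor Fcgr2b (-0.51 ± 0.14) were examples. Of 14 stellate cell and fibroblast markers, 4 rose, 1 fell and 9 did not pass, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.457). Of 10 cholangiocyte and progenitor markers, 2 rose, 3 fell and 5 did not pass, or 2 and 4 adjusted over the list alone (camera adjusted p = 0.175), and the tetraspanin Tspan8 (-2.10 ± 0.40) and the ductal factor Sox9 (-1.27 ± 0.29) fell. None of 4 erythroid markers passed, over all genes or adjusted over the list alone (camera adjusted p = 0.844), and the test direction was down although their median was 0.68. Among tested pancreatic acinar markers 2 rose, 0 fell and 2 did not pass, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.0378 and adjusted p = 0.276 with an estimated correlation, 0.0689 without NFE2L2_MET replicate 3), with the elastase gene Cela1 higher (0.67 ± 0.15). Amy2a5 and Cpb1 had 0 counts throughout, so acinar RNA is not shown. Of 12 immediate early and heat shock genes, which respond to tissue handling, 1 rose, 1 fell and 10 did not pass, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.916), and the test direction was down against a median of 0.02. Among 11 male-biased liver genes 8 fell, 0 rose and 3 did not pass, or 9 and 0 adjusted over the list alone (camera adjusted p = 0.000188 and adjusted p = 0.315 with an estimated correlation). The complement gene C6 (-1.52 ± 0.27) and the oxysterol hydroxylase Cyp7b1 (-1.85 ± 0.35) were among them. Of 10 female-biased genes, 1 rose, 3 fell and 6 did not pass, or 1 and 3 adjusted over the list alone (camera adjusted p = 0.355), and Cyp2b9, from a multi-copy family and so uncertain, fell (-1.27 ± 0.21). Unmapped reads averaged 10.3 ± 1.41% in CTNNB1_NFE2L2_MET and 13.7 ± 0.878% in NFE2L2_MET, and 86 of 123 called named genes kept their call with a term for this share.

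**Figure D2:**
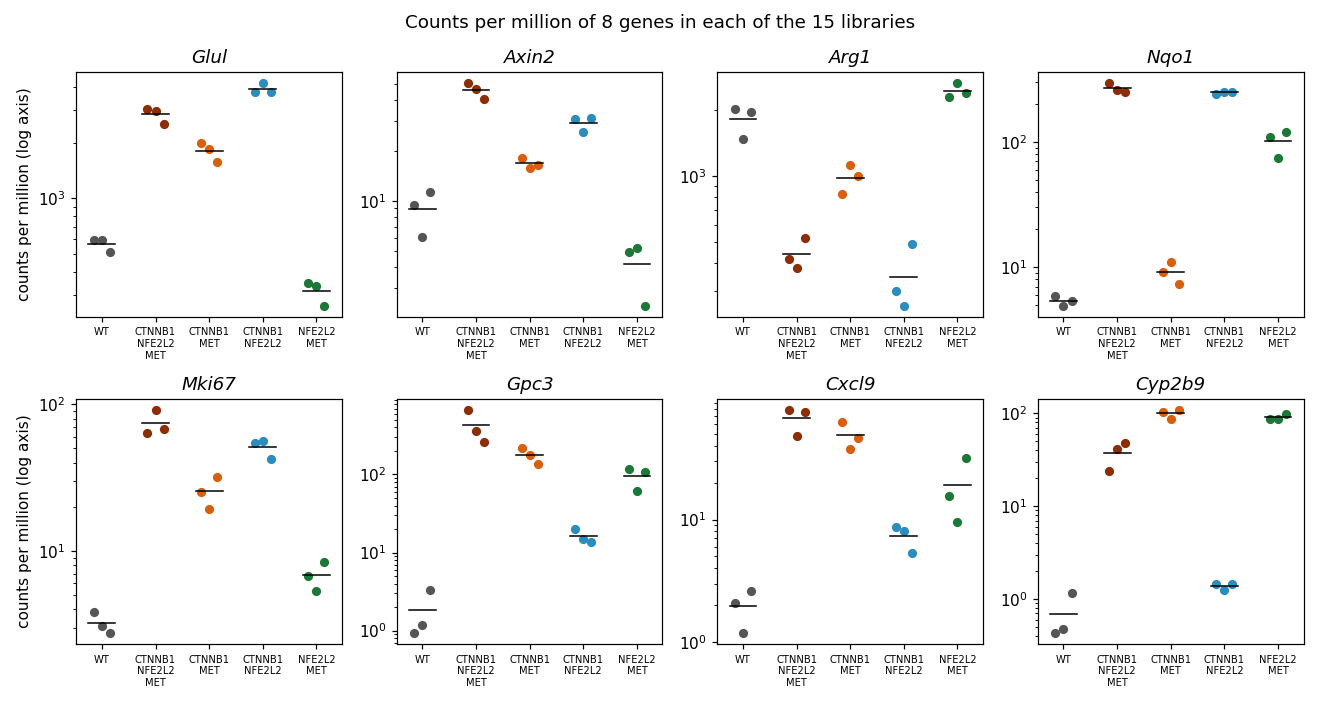
CPM on a log axis for 8 genes (Glul, Axin2, Arg1, Nqo1, Mki67, Gpc3, Cxcl9 and Cyp2b9) in all 15 libraries, 1 point for each library and a bar at the mean of each group of 3. Glul averaged 2850 CPM in CTNNB1_NFE2L2_MET against 313 CPM in NFE2L2_MET, and Nqo1 averaged 9.14 CPM in CTNNB1_MET against 268 CPM in CTNNB1_NFE2L2_MET.

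For NFE2L2 added, CTNNB1_NFE2L2_MET was set against CTNNB1_MET. NRF2 is the transcription factor of the antioxidant response, and the G31 residue lies where KEAP1 binds it for degradation. Its targets make glutathione, supply NADPH and detoxify foreign compounds. The contrast moved 2597 genes up and 2168 down, 1814 of them 2-fold or more. Total-count scaling, with the all-gene median at log2 0.26, gave 4970 higher and 1038 lower.

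NRF2 targets rose almost without exception. Of 35 members 32 rose, 0 fell and 3 did not pass, or 33 and 0 adjusted over the list alone (camera adjusted p = 1.84e-23 and adjusted p = 0.231 with an estimated correlation). Nqo1 (chromosome 8, 107388225 to 107403205) rose 29.5-fold (4.88 ± 0.19), from 9.14 ± 1.78 to 268 ± 23.7 CPM. The sulfiredoxin Srxn1 (4.74 ± 0.24), the carbonyl reductase Cbr3 (6.08 ± 0.31) and the cystine transporter Slc7a11 (6.38 ± 0.47) rose as well. Gclc, the rate-limiting enzyme of glutathione synthesis (3.08 ± 0.23), the UDP-glucose dehydrogenase Ugdh (3.20 ± 0.19) and the NADPH source Me1 (0.89 ± 0.18) followed. The largest rises outside the list were the glutathione peroxidase Gpx2 (7.01 ± 0.34), the keratins Krt76 (7.33 ± 0.42) and Krt5 (6.75 ± 0.51), and the filament protein Tekt5 (5.85 ± 0.29). Strong losses included A1bg, a female-biased secreted protein (-6.24 ± 0.46), the steroid reductase Akr1c18 (-4.34 ± 0.35), the imprinted growth regulator Dlk1 (-4.17 ± 0.38) and the sulfotransferase Sult3a1 (-4.13 ± 0.40). Female-biased genes fell as a list, and of 10 members 6 fell, 1 rose and 3 did not pass, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.00171 and adjusted p = 0.193 with an estimated correlation). Cyp2a4 was the exception and rose (4.21 ± 0.52), with the reservation that near-identical copies share its reads. Of 11 male-biased genes, 8 fell, 0 rose and 3 did not pass, or 9 and 0 adjusted over the list alone (camera adjusted p = 0.000371 and adjusted p = 0.346 with an estimated correlation). The organic anion carrier Slco1a1 (-1.67 ± 0.34) was among them.

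β-catenin and zonal genes shifted as well, although both groups carried S45Y-CTNNB1. Of 15 β-catenin targets, 7 rose, 2 fell and 6 did not pass, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.0751). Nkd1 (1.90 ± 0.20), Axin2 (1.47 ± 0.22) and Sp5 (0.77 ± 0.19) were higher. Of 17 pericentral genes, 5 rose, 8 fell and 4 did not pass, or 5 and 8 adjusted over the list alone (camera adjusted p = 0.425). The caffeine-metabolising Cyp1a2 (2.09 ± 0.22) and Glul (0.66 ± 0.15) rose and the ethanol-metabolising Cyp2e1 fell (-1.15 ± 0.24). Of 17 periportal genes, 14 fell, 0 rose and 3 did not pass, or 14 and 0 adjusted over the list alone (camera adjusted p = 1.91e-06 and adjusted p = 0.276 with an estimated correlation). Cyp2f2 (-2.32 ± 0.46), the histidine lyase Hal (-2.03 ± 0.32), Uroc1 (-1.90 ± 0.23) and Aldh1b1 (-1.38 ± 0.17) were among them. Of 20 hepatocyte secretory and metabolic genes, 15 fell, 0 rose and 5 did not pass, or 15 and 0 adjusted over the list alone (camera adjusted p = 4.56e-08 and adjusted p = 0.231 with an estimated correlation). The fetuin Ahsg (-1.18 ± 0.16) and the tyrosine-degrading Hpd (-1.70 ± 0.23) were examples. Of 7 urea cycle genes, 6 fell, 0 rose and 1 did not pass, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.000248 and adjusted p = 0.26 with an estimated correlation). Asl (-1.59 ± 0.21) and Otc (-1.65 ± 0.29) were among them. Bile acid genes included 7 that fell, 1 that rose and 6 that did not pass, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.000636 and adjusted p = 0.282 with an estimated correlation). The growth factor receptor Fgfr4 (-0.96 ± 0.11) and Slc10a1 (-1.48 ± 0.22) were lower. Fatty acid synthesis genes included 10 that fell, 1 that rose and 3 that did not pass, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.00025 and adjusted p = 0.267 with an estimated correlation). The carbohydrate-sensing factor Mlxipl was lower (-0.83 ± 0.17). Of 15 fatty acid oxidation genes, 7 fell, 2 rose and 6 did not pass, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.0203 and adjusted p = 0.431 with an estimated correlation). The lipid chaperone Fabp1 (-1.92 ± 0.23) and its regulator Ppara (-0.82 ± 0.15) were among them. Of 12 glycolysis genes, 6 rose, 0 fell and 6 did not pass, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.0203 and adjusted p = 0.462 with an estimated correlation, 0.083 without CTNNB1_NFE2L2_MET replicate 1). Pkm (2.31 ± 0.27) and the muscle-type aldolase Aldoa (1.22 ± 0.21) were higher. Of 24 cell cycle genes, 23 rose, 0 fell and 1 did not pass, or 23 and 1 adjusted over the list alone (camera adjusted p = 7.42e-10 and adjusted p = 0.26 with an estimated correlation). Bub1 of the spindle checkpoint (2.81 ± 0.31), Cdk1 (1.75 ± 0.20) and Mki67 (1.53 ± 0.20) were among them.

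Macrophage transcripts were higher in the group with mutant NRF2. Of 17 macrophage and Kupffer cell markers 13 rose, 0 fell and 4 did not pass, or 13 and 0 adjusted over the list alone (camera adjusted p = 3.62e-05 and adjusted p = 0.309 with an estimated correlation). The complement genes C1qa (1.00 ± 0.15), C1qb (1.11 ± 0.15) and C1qc (1.02 ± 0.17) and the growth factor receptor Csf1r (0.94 ± 0.16) rose. Interferon response genes included 9 that rose, 1 that fell and 10 that did not pass, or 12 and 1 adjusted over the list alone (camera adjusted p = 0.00798 and adjusted p = 0.431 with an estimated correlation). The nucleotide-sensing family member Oasl2 (1.93 ± 0.33) and the antiviral Ifit2 (1.37 ± 0.26) were higher. Checkpoint genes included 3 that rose, 0 that fell and 4 that did not pass, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.0489 and adjusted p = 0.276 with an estimated correlation, 0.106 without CTNNB1_MET replicate 3), and Cd274 did not pass (0.82 ± 0.32, adjusted p = 0.0582). The class I genes H2-K1 (-0.53 ± 0.13) and B2m (-0.53 ± 0.12) fell while the class II chaperone H2-DMa rose (1.17 ± 0.20), and the antigen presentation list was not called (camera adjusted p = 0.393). T and NK cell markers were not called either (camera adjusted p = 0.898), and Zap70, a kinase of the T cell receptor, fell (-1.97 ± 0.27). The monocyte attractants Ccl2 (2.63 ± 0.54) and Ccl6 (1.79 ± 0.35) rose although the chemokine list did not pass (camera adjusted p = 0.202). ERK output genes were mixed (camera adjusted p = 0.241), with the phosphatase Dusp4 higher (2.29 ± 0.23) and the feedback inhibitor Spry4 lower (-1.59 ± 0.23). The adhesion molecule Epcam, a progenitor marker, rose 17.3-fold (4.11 ± 0.30). Unmapped reads averaged 10.3% here against 17.2 ± 1.75% in CTNNB1_MET, and a term for this share gave 576 called genes instead of 4765, with 37 of 114 named genes still called.

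For MET added, CTNNB1_NFE2L2_MET was set against CTNNB1_NFE2L2. MET signals through the RAS and ERK cascade, whose output includes its own feedback inhibitors. The unmapped share was alike in these groups, 10.3% and 10.7 ± 1.03%, and with a term for it the total was 3485 called genes. The contrast moved 1853 genes up and 1667 down, 958 of them 2-fold or more. Without CTNNB1_NFE2L2 replicate 2 these were 1141 up and 1118 down.

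ERK output genes rose as a group. Of 15 members 10 rose, 0 fell and 5 did not pass, or 11 and 0 adjusted over the list alone (camera adjusted p = 1.55e-05 and adjusted p = 0.26 with an estimated correlation). The ETS factor Etv5 (1.70 ± 0.19), the feedback inhibitors Spry4 (1.94 ± 0.27) and Spred1 (1.04 ± 0.13) and the urokinase receptor Plaur (2.10 ± 0.40) rose. Of 15 oncofetal and tumour markers, 8 rose, 0 fell and 7 did not pass, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.001 and adjusted p = 0.267 with an estimated correlation). Gpc3 (chromosome X, 52272426 to 52613974) rose 26.6-fold (4.73 ± 0.45), from 16.1 ± 3.34 to 428 ± 211 CPM, and Afp (3.15 ± 0.49), Prom1 (2.98 ± 0.24), Robo1 (1.89 ± 0.25) and the Golgi protein Golm1 (0.88 ± 0.12) rose as well. Other large rises were Krt5 (6.72 ± 0.50), Cdh17 (6.56 ± 0.41), Tspan8 (4.27 ± 0.51) and the interferon-induced GTPase Tgtp1, which has a near-identical copy (4.25 ± 0.35). Other large losses included the Wnt ligand Wnt4 (-5.13 ± 0.42), the secreted Olfm1 (-4.00 ± 0.37) and Cyp2c38 of a multi-copy family (-3.68 ± 0.28). Of 10 cholangiocyte and progenitor markers, 3 rose, 0 fell and 7 did not pass, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.0108 and adjusted p = 0.267 with an estimated correlation). The periportal list did not pass (camera adjusted p = 0.717), and its member Cdh1, the epithelial cadherin, rose (1.66 ± 0.24). Of 17 pericentral genes, 6 fell, 2 rose and 9 did not pass, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0139 and adjusted p = 0.372 with an estimated correlation). The glutamate transporter Slc1a2 (-1.44 ± 0.19), the cation transporter Slc22a3 (-2.38 ± 0.19) and the aminotransferase Oat (-1.13 ± 0.21) fell and Lect2 rose (0.95 ± 0.19). β-catenin targets were not called as a list (camera adjusted p = 0.891), with Apcdd1, a Wnt antagonist, lower (-1.57 ± 0.31) and Lgr5 not passing (0.05 ± 0.22, adjusted p = 0.905). Of 35 NRF2 targets, 8 fell, 1 rose and 26 did not pass, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.0132 and adjusted p = 0.606 with an estimated correlation). The ferritin light chain Ftl1 (-1.05 ± 0.23) and the epoxide hydrolase Ephx1 (-0.77 ± 0.18) were lower, while Nqo1 did not pass (0.11 ± 0.15, adjusted p = 0.627).

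Hepatocyte genes moved in separate directions. Alb, the main plasma protein, rose 3.06-fold (1.61 ± 0.21) and Ahsg rose (0.89 ± 0.16), while Hpd fell (-1.06 ± 0.22), and the secretory list was not called (camera adjusted p = 0.427). Of 14 bile acid genes, 7 fell, 0 rose and 7 did not pass, or 9 and 0 adjusted over the list alone (camera adjusted p = 0.000208 and adjusted p = 0.276 with an estimated correlation). The canalicular pumps Abcb4 (-1.06 ± 0.17) and Abcb11 (-1.01 ± 0.19) and the sterol hydroxylase Cyp8b1 (-2.03 ± 0.40) were among them. Of 11 male-biased genes, 5 fell, 0 rose and 6 did not pass, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.00326 and adjusted p = 0.431 with an estimated correlation). Cyp4a12b fell the most of all named genes (-5.51 ± 0.36), with reads shared between close copies. The female-biased list was not called (camera adjusted p = 0.229), although its member Cyp2b9 rose 27.1-fold (4.76 ± 0.28), also in a multi-copy family. Fatty acid synthesis genes were not called as a list (camera adjusted p = 0.457), with the elongase Elovl6 (1.07 ± 0.18) and the liver pyruvate kinase Pklr (0.72 ± 0.15) higher and the carboxylase Acacb lower (-1.35 ± 0.28). Cell cycle genes were not called as a list (camera adjusted p = 0.263).

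Antigen presentation genes were higher in the group with the MET transgene. Of 16 members 13 rose, 0 fell and 3 did not pass, or 14 and 0 adjusted over the list alone (camera adjusted p = 1.53e-08 and adjusted p = 0.231 with an estimated correlation). The class II activator Ciita (2.32 ± 0.32), the immunoproteasome subunit Psmb8 (1.49 ± 0.20), the peptide transporter Tap1 (1.15 ± 0.18) and H2-DMb1 (1.82 ± 0.29) rose. Chemokine genes included 3 that rose, 0 that fell and 7 that did not pass, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.00542 and adjusted p = 0.276 with an estimated correlation), with the T cell attractant Cxcl9 rising from 7.34 ± 1.81 to 67.1 ± 16.8 CPM (3.19 ± 0.41). T and NK cell markers included 4 that rose, 0 that fell and 8 that did not pass, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.00225 and adjusted p = 0.282 with an estimated correlation). Of 9 dendritic cell markers, 4 rose, 0 fell and 5 did not pass, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.0383 and adjusted p = 0.26 with an estimated correlation), and the integrin Itgax of dendritic cells and macrophages rose (2.11 ± 0.37). The antibody joining chain Jchain (4.36 ± 0.61) and the monocyte receptor Ccr2 (2.29 ± 0.42) rose, while the B and plasma cell list did not pass (camera adjusted p = 0.0737). Among interferon genes Gbp2 (1.60 ± 0.22) and Gbp3 (1.14 ± 0.25) rose without a call for the list (camera adjusted p = 0.0922). Of 14 stellate and fibroblast markers, 5 rose, 0 fell and 9 did not pass, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.000551 and adjusted p = 0.276 with an estimated correlation). The matrix protein Lum (1.36 ± 0.19) and the secreted Reln (3.15 ± 0.23) were among them. All 4 erythroid markers fell (camera adjusted p = 0.000247 and adjusted p = 0.175 with an estimated correlation), with 0 higher and 4 lower adjusted over the list alone, the most certain being the haem synthase Alas2 (-1.19 ± 0.16). Of 12 immediate early and heat shock genes, 2 fell, 0 rose and 10 did not pass, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.0477 and adjusted p = 0.589 with an estimated correlation, 0.376 without CTNNB1_NFE2L2 replicate 1). CTNNB1_NFE2L2 replicate 1 stood apart here, with Hspa1b at 356 CPM against 51.1 and 51.3 CPM in replicates 2 and 3, and without it no member passed, also adjusted over the list alone.

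The 3 models with S45Y-CTNNB1 were also set together against NFE2L2_MET, the only model without it. The contrast averages the 3 models, so a large change in 1 of them can carry it. The contrast moved 1806 genes up and 1977 down, 1151 of them 2-fold or more, and the total was 3586 genes with a term for the unmapped share. Total-count scaling, with the all-gene median at log2 0.25, gave 4963 higher and 829 lower. Of 15 β-catenin targets, 13 rose, 1 fell and 1 did not pass, or 14 and 1 adjusted over the list alone (camera adjusted p = 5.89e-15 and adjusted p = 0.175 with an estimated correlation). Of 17 pericentral genes, 12 rose, 1 fell and 4 did not pass, or 12 and 1 adjusted over the list alone (camera adjusted p = 7.16e-10 and adjusted p = 0.193 with an estimated correlation). Nkd1 (chromosome 8, 88521342 to 88594887) rose 27.9-fold (4.80 ± 0.23), Glul 8.69-fold (3.12 ± 0.15), Rhbg 13.6-fold (3.77 ± 0.21) and Slc1a2 7.68-fold (2.94 ± 0.18), and the transcription factor Tcf7, a partner of β-catenin, rose as well (2.60 ± 0.19). Of 17 periportal genes, 13 fell, 0 rose and 4 did not pass, or 13 and 0 adjusted over the list alone (camera adjusted p = 6.09e-10 and adjusted p = 0.231 with an estimated correlation). Aldh1b1 (-2.58 ± 0.12), Arg1 (-2.20 ± 0.16) and Cyp2f2 (-2.59 ± 0.33) were lower. Cell cycle genes included 22 that rose, 0 that fell and 2 that did not pass, or 23 and 0 adjusted over the list alone (camera adjusted p = 8.29e-18 and adjusted p = 0.231 with an estimated correlation), with Mki67 rising 6.71-fold (2.75 ± 0.20). Of 14 fatty acid synthesis genes, 10 fell, 1 rose and 3 did not pass, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.000802 and adjusted p = 0.276 with an estimated correlation). Acly (-1.32 ± 0.11) and the regulator Srebf1 (-0.94 ± 0.17) were among them. Of 12 acute phase genes, 7 fell, 0 rose and 5 did not pass, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.00185 and adjusted p = 0.459 with an estimated correlation). Without NFE2L2_MET replicate 2, which was high in Saa1, 3 fell and 9 did not pass, or 5 adjusted over the list alone (camera adjusted p = 0.0143 and adjusted p = 0.558 with an estimated correlation). Orm1 was an example (-1.80 ± 0.36), and the chemokine Cxcl1 fell as well (-3.08 ± 0.45). Of 3 neutrophil markers, 3 fell, 0 rose and 0 did not pass, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.0205 and adjusted p = 0.303 with an estimated correlation), with the colony-stimulating factor receptor Csf3r the most stable (-1.31 ± 0.28). S100a9 stood at 3.77, 13.3 and 3.61 CPM in NFE2L2_MET replicates 1, 2 and 3, and without replicate 2 all 3 markers still fell, also adjusted over the list alone (camera adjusted p = 0.0429 and adjusted p = 0.343 with an estimated correlation). Of 10 cholangiocyte and progenitor markers, 5 fell, 0 rose and 5 did not pass, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.0111 and adjusted p = 0.268 with an estimated correlation). Tspan8 was lower (-4.09 ± 0.30). The lower value of Epcam (-1.99 ± 0.19) came mainly from CTNNB1_MET, which lacks G31A-NFE2L2, with 1.60 ± 0.668 CPM against 27.2 ± 2.96 in CTNNB1_NFE2L2_MET, 20.3 ± 6.51 in CTNNB1_NFE2L2 and 37.8 ± 6.86 in NFE2L2_MET. Of 15 endothelial markers, 6 fell, 0 rose and 9 did not pass, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.0157 and adjusted p = 0.431 with an estimated correlation). The central-vein signal Rspo3 (-1.02 ± 0.22) was among them. T and NK cell markers included 7 that rose, 0 that fell and 5 that did not pass, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.00681 and adjusted p = 0.31 with an estimated correlation). Spink1 (-6.08 ± 0.25), Tff3 (-5.34 ± 0.21) and Slc45a1 (-5.34 ± 0.23) were higher in NFE2L2_MET. The average does not bear on NRF2 targets, since 1 of the 3 models lacks G31A-NFE2L2. Nqo1 averaged 268 ± 23.7 CPM in CTNNB1_NFE2L2_MET, 248 ± 4.52 in CTNNB1_NFE2L2 and 9.14 ± 1.78 in CTNNB1_MET, against 100.6 ± 23.9 in NFE2L2_MET.

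A stricter set held genes higher in each CTNNB1 model than in both WT and NFE2L2_MET. It counted 245 genes, of which 19 belonged to the β-catenin target or pericentral lists. Many cell cycle genes were also in the set, among them Mki67, Top2a, Cdk1, Plk1 and Ccna2. The set is therefore not made of β-catenin targets alone. With a term for the unmapped share the set counted 36 genes. The carbonic anhydrase Car4 (chromosome 11, 84957754 to 84966054) averaged 36.9 ± 12.1, 11.4 ± 1.34 and 12.1 ± 5.27 CPM in CTNNB1_NFE2L2_MET, CTNNB1_MET and CTNNB1_NFE2L2, against 0.155 ± 0.161 CPM in WT and 0.275 ± 0.203 CPM in NFE2L2_MET. The non-coding RNAs Rian (chromosome 12, 109603945 to 109661716) and Meg3 (chromosome 12, 109540996 to 109571729) lie in the imprinted Dlk1 region, as does Mirg, a microRNA host in the set. Meg3 averaged 149 ± 22.0, 279 ± 102 and 251 ± 32.7 CPM in the same order, against 7.43 ± 0.49 and 6.56 ± 3.43 CPM. Nxpe2 averaged 107 ± 13.0, 77.2 ± 15.8 and 92.8 ± 5.44 CPM, against 6.31 ± 1.75 and 4.29 ± 1.33 CPM.

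The comparisons with WT describe the whole distance between a model liver and wild-type liver. They also carry differences between the WT samples themselves and in sequencing. Unmapped reads averaged 22.9 ± 3.05% in WT and 10.3 to 17.2% in the models, and 91.1% of the variance of this share lay between groups. A term for it raised the median standard error 2.91-fold in CTNNB1_NFE2L2_MET, 1.59-fold in CTNNB1_MET, 2.82-fold in CTNNB1_NFE2L2 and 2.23-fold in NFE2L2_MET against WT. Named genes still called with the term were 33 of 135 in CTNNB1_NFE2L2_MET, 35 of 129 in CTNNB1_NFE2L2 and 15 of 109 in NFE2L2_MET, while in CTNNB1_MET 48 kept and 63 lost the call. WT replicate 2 held an acute phase pattern, with the serum amyloid gene Saa1 at 46.8, 8052 and 99.3 CPM and the lipocalin Lcn2 at 1.73, 358 and 7.25 CPM in WT replicates 1, 2 and 3. The cartilage collagen Col2a1 stood at 192, 192 and 46.0 CPM in the same libraries against 13.6 to 76.8 CPM in the models. Total-count scaling shifted the all-gene median to log2 0.22, -0.03, 0.17 and -0.13 in CTNNB1_NFE2L2_MET, CTNNB1_MET, CTNNB1_NFE2L2 and NFE2L2_MET.

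CTNNB1_NFE2L2_MET against WT combined the outputs of all 3 pathways. The model moved 3739 genes up and 3300 down, 3186 of them 2-fold or more, and total-count scaling gave 5226 and 1892. Of 35 NRF2 targets, 31 rose, 1 fell and 3 did not pass, or 31 and 1 adjusted over the list alone (camera adjusted p = 1.05e-14 and adjusted p = 0.231 with an estimated correlation). Nqo1 (5.64 ± 0.20) and the glutathione transferase Gstm2 (3.98 ± 0.18) were higher. Of 15 β-catenin targets, 13 rose, 1 fell and 1 did not pass, or 13 and 1 adjusted over the list alone (camera adjusted p = 4.44e-06 and adjusted p = 0.248 with an estimated correlation), with Nkd1 (4.13 ± 0.23) and the T-box factor Tbx3 (1.67 ± 0.17) higher, and Rhbg rose (4.20 ± 0.23). Of 17 pericentral genes, 9 rose, 6 fell and 2 did not pass, or 9 and 6 adjusted over the list alone (camera adjusted p = 0.12). Glul rose (2.33 ± 0.15) and Cyp2e1 fell (-1.26 ± 0.24). Of 15 ERK output genes, 11 rose, 1 fell and 3 did not pass, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.00532 and adjusted p = 0.386 with an estimated correlation). Dusp4 (3.43 ± 0.25) and Dusp6 (2.52 ± 0.25) were among them. All 24 cell cycle genes rose, also adjusted over the list alone (camera adjusted p = 1.38e-14 and adjusted p = 0.231 with an estimated correlation), with Ccna2 (3.99 ± 0.27) an example. Of 15 tumour markers, 9 rose, 1 fell and 5 did not pass, or 11 and 1 adjusted over the list alone (camera adjusted p = 8.35e-05 and adjusted p = 0.231 with an estimated correlation). Golm1 rose 28.4-fold (4.83 ± 0.15) and the surface protein Ly6d 297-fold (8.21 ± 0.45), while Gpc3 rose with dependence on 1 library (7.86 ± 0.55, 8.63 without WT replicate 3). Of 11 male-biased genes, 10 fell, 0 rose and 1 did not pass, or 10 and 0 adjusted over the list alone (camera adjusted p = 6.27e-05 and adjusted p = 0.303 with an estimated correlation). All 7 tested urea cycle genes fell, with 0 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.00027 and adjusted p = 0.26 with an estimated correlation). Cholesterol synthesis genes included 7 that fell, 0 that rose and 7 that did not pass, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.00561 and adjusted p = 0.536 with an estimated correlation). Insig1 (-1.99 ± 0.23) and Dhcr7 (-1.93 ± 0.25) led this list. Of 20 interferon response genes, 19 rose, 0 fell and 1 did not pass, or 19 and 0 adjusted over the list alone (camera adjusted p = 8.85e-08 and adjusted p = 0.231 with an estimated correlation), led by Usp18 (3.88 ± 0.28). Of 17 macrophage markers, 15 rose, 0 fell and 2 did not pass, or 15 and 0 adjusted over the list alone (camera adjusted p = 6.81e-06 and adjusted p = 0.282 with an estimated correlation), and Cd5l was higher (1.78 ± 0.19). Antigen presentation genes included 13 that rose, 0 that fell and 3 that did not pass, or 14 and 0 adjusted over the list alone (camera adjusted p = 4.93e-05 and adjusted p = 0.276 with an estimated correlation). Of 7 checkpoint genes, 5 rose, 0 fell and 2 did not pass, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.0109 and adjusted p = 0.231 with an estimated correlation). Cd274 rose (2.02 ± 0.35), and the chemokine Cxcl9 rose (5.10 ± 0.48). Among tested pancreatic acinar markers 3 rose, 0 fell and 1 did not pass, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.0451 and adjusted p = 0.282 with an estimated correlation, 0.0741 without WT replicate 3), where Pnliprp1 went from 0 counts in WT to 1.80 ± 0.654 CPM and Amy2a5 stayed at 0.

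CTNNB1_MET had the fewest changed genes against WT in the main fit, an order that did not hold with a term for the unmapped share (540 genes, against 141 in NFE2L2_MET). It moved 1552 genes up and 877 down, 1059 of them 2-fold or more. Without CTNNB1_MET replicate 1 these were 971 up and 323 down, and with only the libraries of the contrast 1027 up and 478 down. Of 15 β-catenin targets, 12 rose, 0 fell and 3 did not pass, or 14 and 0 adjusted over the list alone (camera adjusted p = 5.91e-11 and adjusted p = 0.231 with an estimated correlation). Tcf7 (1.94 ± 0.20), Nkd1 (2.22 ± 0.22) and Notum (1.05 ± 0.13) were higher. Of 17 pericentral genes, 7 rose, 0 fell and 10 did not pass, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.000263 and adjusted p = 0.26 with an estimated correlation). The carboxylate transporter Slc13a3 (2.62 ± 0.23), Rhbg (3.55 ± 0.22) and Lect2 (2.63 ± 0.20) were higher. NRF2 targets were not called as a list (camera adjusted p = 0.457). Of 10 female-biased genes, 7 rose, 0 fell and 3 did not pass, or 7 and 0 adjusted over the list alone (camera adjusted p = 4.22e-08 and adjusted p = 0.0278 with an estimated correlation), and this was the only list of the 256 tests that passed with an estimated correlation. A1bg rose 66.3-fold (6.05 ± 0.46), and Cyp2b9 went from 0.687 ± 0.406 to 100 ± 11.1 CPM (7.17 ± 0.32, 7.76 without WT replicate 3). Of 15 ERK output genes, 7 rose, 0 fell and 8 did not pass, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.000953 and adjusted p = 0.309 with an estimated correlation). Dusp6 (1.92 ± 0.25) and the ETS factor Etv4 (3.04 ± 0.54) were higher. Of 24 cell cycle genes, 23 rose, 0 fell and 1 did not pass, or 23 and 0 adjusted over the list alone (camera adjusted p = 3.46e-17 and adjusted p = 0.231 with an estimated correlation), with the replication helicase Mcm3 higher (1.55 ± 0.20). Of 15 tumour markers, 10 rose, 0 fell and 5 did not pass, or 10 and 0 adjusted over the list alone (camera adjusted p = 2.16e-10 and adjusted p = 0.175 with an estimated correlation). Dlk1 (5.52 ± 0.44) and Prom1 (6.46 ± 0.33) were higher. Of 20 interferon response genes, 13 rose, 0 fell and 7 did not pass, or 16 and 0 adjusted over the list alone (camera adjusted p = 1.19e-09 and adjusted p = 0.231 with an estimated correlation). Of 16 antigen presentation genes, 13 rose, 0 fell and 3 did not pass, or 15 and 0 adjusted over the list alone (camera adjusted p = 4.59e-09 and adjusted p = 0.231 with an estimated correlation). Bst2, a restriction factor (1.04 ± 0.10), and Psmb8 (1.64 ± 0.20) were examples. The secretory gene Ahsg rose (1.16 ± 0.16) without a call for its list (camera adjusted p = 0.844). Of 14 stellate and fibroblast markers, 7 fell, 1 rose and 6 did not pass, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.0151 and adjusted p = 0.42 with an estimated correlation, 0.0783 without WT replicate 2), although Reln rose (2.85 ± 0.23). The fall is uncertain, since WT replicates 1 and 2, which held the cartilage signal, were also high in list members. Col1a1 stood at 318, 326 and 54.5 CPM and Col1a2 at 230, 228 and 43.3 CPM in WT replicates 1, 2 and 3, against 51.9, 55.2 and 72.2 CPM and 45.5, 54.8 and 62.3 CPM in CTNNB1_MET. The acute phase list was not called (camera adjusted p = 0.951), and its test direction was up against a median of -0.28.

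CTNNB1_NFE2L2 lacks the MET transgene and holds mutant β-catenin and mutant NRF2. It moved 3456 genes up and 3411 down, 2860 of them 2-fold or more, and total-count scaling gave 4507 and 2127. Of 35 NRF2 targets, 32 rose, 1 fell and 2 did not pass, or 32 and 1 adjusted over the list alone (camera adjusted p = 8.29e-18 and adjusted p = 0.231 with an estimated correlation). Nqo1 (5.53 ± 0.19) and Gstm2 (4.62 ± 0.18) were higher. Of 15 β-catenin targets, 14 rose, 1 fell and 0 did not pass, or 14 and 1 adjusted over the list alone (camera adjusted p = 6.87e-07 and adjusted p = 0.231 with an estimated correlation). Among the 17 pericentral genes, 10 rose, 5 fell and 2 did not pass, or 10 and 5 adjusted over the list alone (camera adjusted p = 0.00561 and adjusted p = 0.31 with an estimated correlation), with Slc22a3 rising 19.1-fold (4.25 ± 0.22). ERK output genes were not called as a list (camera adjusted p = 0.844), and Spry4 fell (-2.62 ± 0.27). Of 17 periportal genes, 15 fell, 0 rose and 2 did not pass, or 15 and 0 adjusted over the list alone (camera adjusted p = 1.55e-07 and adjusted p = 0.267 with an estimated correlation). Arg1 (-2.38 ± 0.23) and Hal (-3.53 ± 0.34) were lower. The thyroid hormone deiodinase Dio1 fell 33.6-fold (-5.07 ± 0.63) and the anion transporter Slc22a7 fell 23.7-fold (-4.57 ± 0.51). Alb fell (-1.59 ± 0.21), and hepatocyte secretory genes included 16 that fell, 0 that rose and 4 that did not pass, or 17 and 1 adjusted over the list alone (camera adjusted p = 3.45e-06 and adjusted p = 0.231 with an estimated correlation). Fatty acid synthesis genes included 7 that fell, 1 that rose and 6 that did not pass, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.00543 and adjusted p = 0.32 with an estimated correlation). Srebf1 was lower (-2.03 ± 0.22). Of 20 interferon response genes, 16 rose, 1 fell and 3 did not pass, or 16 and 1 adjusted over the list alone (camera adjusted p = 6.13e-06 and adjusted p = 0.26 with an estimated correlation), with Isg15 (1.68 ± 0.20), Rsad2 (2.54 ± 0.31) and Ifi44 (3.94 ± 0.50) higher, whereas antigen presentation was not called (camera adjusted p = 0.532). Of 14 stellate and fibroblast markers, 9 fell, 1 rose and 4 did not pass, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.00874 and adjusted p = 0.386 with an estimated correlation). Dcn (-1.70 ± 0.24) and Lox (-2.69 ± 0.40) were among them. Part of this fall is uncertain, since several members were high in the WT libraries with the cartilage signal. Lox stood at 194, 191 and 51.7 CPM, Col3a1 at 129, 119 and 32.1 CPM and Timp1 at 12.4, 14.2 and 3.59 CPM in WT replicates 1, 2 and 3, and Col1a1 and Col1a2 had the same order. Erythroid markers were not called (camera adjusted p = 0.135), although the red cell anion exchanger Slc4a1 rose (6.01 ± 0.58). The T and NK cell list did not pass (camera adjusted p = 0.826).

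NFE2L2_MET is the model without S45Y-CTNNB1 and holds mutant NRF2 with the growth factor receptor. It moved 1909 genes up and 1394 down, 1255 of them 2-fold or more, and total-count scaling gave 1372 and 2517. Without NFE2L2_MET replicate 3 it moved 1363 up and 774 down, and with only the libraries of the contrast 1314 up and 801 down. Of 15 β-catenin targets, 5 fell, 0 rose and 10 did not pass, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.00161 and adjusted p = 0.31 with an estimated correlation). Sp5 (-2.06 ± 0.30) and Notum (-0.83 ± 0.13) were lower. Among the 17 pericentral genes, 12 fell, 0 rose and 5 did not pass, or 13 and 0 adjusted over the list alone (camera adjusted p = 1.3e-06 and adjusted p = 0.231 with an estimated correlation). Cyp2e1 (-1.41 ± 0.24), Oat (-1.18 ± 0.21) and Glul (-0.86 ± 0.15) were lower. Periportal genes were not called as a list (camera adjusted p = 0.563), while Aldh1b1 rose (1.54 ± 0.17). Of 35 NRF2 targets, 29 rose, 1 fell and 5 did not pass, or 31 and 1 adjusted over the list alone (camera adjusted p = 2.76e-18 and adjusted p = 0.231 with an estimated correlation), with Nqo1 rising 18.7-fold (4.23 ± 0.19) and Srxn1 20.5-fold (4.36 ± 0.24). Of 15 ERK output genes, 6 rose, 0 fell and 9 did not pass, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.0231 and adjusted p = 0.459 with an estimated correlation, 0.0774 without NFE2L2_MET replicate 1). Dusp4 (2.91 ± 0.25) and Dusp6 (1.96 ± 0.25) were higher. Of 24 cell cycle genes, 12 rose, 0 fell and 12 did not pass, or 12 and 0 adjusted over the list alone (camera adjusted p = 8.93e-05 and adjusted p = 0.391 with an estimated correlation). The ribonucleotide reductase Rrm2 (1.27 ± 0.20) and Mki67 (1.09 ± 0.25) were higher. Of 15 tumour markers, 7 rose, 0 fell and 8 did not pass, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.000119 and adjusted p = 0.233 with an estimated correlation), with Golm1 (4.26 ± 0.15) and Ly6d (5.55 ± 0.43) higher, and Epcam rose 48.3-fold (5.59 ± 0.34). Bile acid genes included 7 that fell, 0 that rose and 7 that did not pass, or 10 and 0 adjusted over the list alone (camera adjusted p = 0.000245 and adjusted p = 0.276 with an estimated correlation). Abcb11 (-1.09 ± 0.19) and Cyp27a1 (-1.03 ± 0.20) were lower. Macrophage markers included 15 that rose, 0 that fell and 2 that did not pass, or 16 and 0 adjusted over the list alone (camera adjusted p = 8.46e-09 and adjusted p = 0.248 with an estimated correlation), and the lysozyme Lyz2 was higher (1.84 ± 0.23). Of 3 neutrophil markers, 3 rose, 0 fell and 0 did not pass, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.0321 and adjusted p = 0.316 with an estimated correlation, 0.066 without NFE2L2_MET replicate 2). Without NFE2L2_MET replicate 2, 1 rose and 2 did not pass, or 2 and 0 adjusted over the list alone. Chemokine genes included 6 that rose, 0 that fell and 4 that did not pass, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.000693 and adjusted p = 0.248 with an estimated correlation). Ccl2 (3.73 ± 0.69) and Cxcl16 (1.00 ± 0.19) were higher. Endothelial markers included 5 that rose, 0 that fell and 10 that did not pass, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.0438 and adjusted p = 0.493 with an estimated correlation, 0.123 without WT replicate 1), with the hyaluronan receptor Lyve1 higher (2.26 ± 0.35). Alb (1.28 ± 0.20) and Acaca (1.02 ± 0.13) rose, and the vasopressin receptor Avpr1a (-2.08 ± 0.23) and the clock repressor Nr1d1 (-2.07 ± 0.49) fell.

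**Figure D3:**
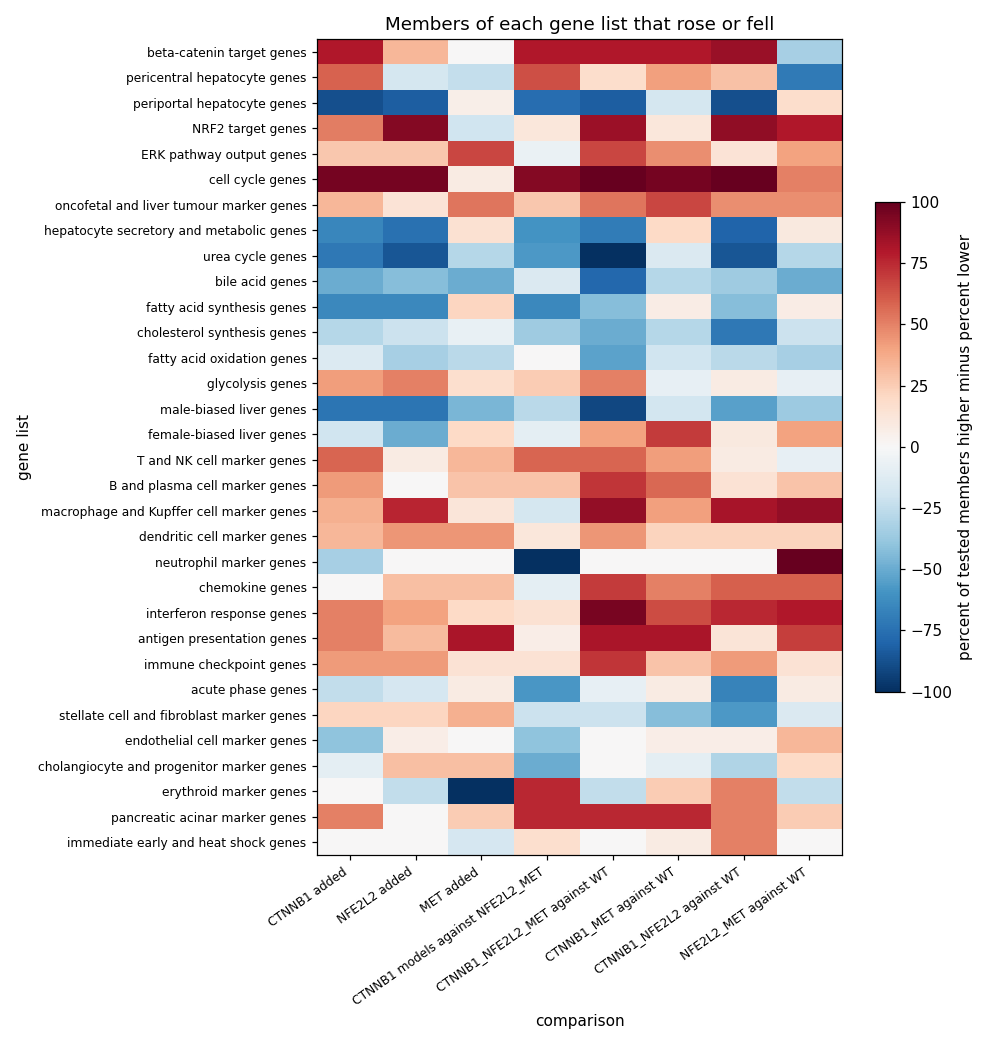
Heatmap of 32 gene lists by 8 contrasts, each cell the percent of tested members called higher minus the percent called lower. β-catenin target genes had 13 of 15 members higher with CTNNB1 added and 0 higher with 5 lower in NFE2L2_MET against WT.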

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

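Pairs of models were compared for genes that differed from WT in opposite directions and also differed directly between the models. Each pair was singled out because the groups disagreed on such genes. CTNNB1_NFE2L2_MET and CTNNB1_MET had 42 of them, CTNNB1_NFE2L2_MET and CTNNB1_NFE2L2 had 85, and CTNNB1_NFE2L2_MET and NFE2L2_MET had 85. CTNNB1_MET and CTNNB1_NFE2L2 had 102, CTNNB1_MET and NFE2L2_MET had 50, and CTNNB1_NFE2L2 and NFE2L2_MET had 186. Genes called in the same direction against WT in both models of a pair numbered 2008, 4792, 2605, 1718, 1250 and 2176 in the same order, so opposite calls were the smaller part in each pair. Both models of a pair share the WT libraries, which pushes calls to the same side. The pairs with NFE2L2_MET included Glul, Axin2, Nkd1, Sp5 and Tcf7, and the pair of CTNNB1_NFE2L2_MET and CTNNB1_MET included Aox1, Ephx1, Spry4, Igf2 and Gsr. CTNNB1_NFE2L2 and NFE2L2_MET also differed in Alb, Cxcl1, Abcb4 and F9.

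Reads assigned to more than 1 gene were singled out because this share was not used in any test and differed from WT. It averaged 1.87% in CTNNB1_NFE2L2_MET, 1.84% in CTNNB1_MET, 1.93% in CTNNB1_NFE2L2 and 1.73% in NFE2L2_MET, against 1.53% in WT. Which genes these reads belong to cannot be read from the counts.

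The tests by regrouping libraries were set before the results were seen. Only 10 ways exist to split 3 and 3 libraries, too few for a share under 0.05, and in each contrast 1 split, the real one, reached the real count. The real and the highest other counts were 4325 and 29 for CTNNB1 added, 4765 and 0 for NFE2L2 added, and 3520 and 0 for MET added. Against WT they were 7039 and 0 in CTNNB1_NFE2L2_MET, 2429 and 0 in CTNNB1_MET, 6867 and 3 in CTNNB1_NFE2L2, and 3303 and 207 in NFE2L2_MET. For the CTNNB1 models against NFE2L2_MET 1 of 100 splits reached 3783, and the highest other count was 1247. For the genes higher in each CTNNB1 model 1 of 100 splits reached 245, and the highest other count was 0. The other splits put libraries of different groups together, which widens the spread within groups and lowers the counts. The count of 1247 came from a split that held all CTNNB1_NFE2L2_MET libraries together. Real and other counts are therefore not like for like, and the gaps do not single out NFE2L2_MET or the CTNNB1 models.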

How the results depend on the processing

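Most counts of changed genes stayed within 1.5-fold under the settings chosen in advance. With only the libraries of the contrast, CTNNB1_MET against WT had 1505 changed genes and NFE2L2_MET against WT 2115, and the cause was not tested. Leaving out 1 library gave 3241 to 4122 genes for CTNNB1 added, 3630 to 4463 for NFE2L2 added, 2259 to 3240 for MET added and 2577 to 3841 for the CTNNB1 models against NFE2L2_MET. Against WT it gave 6092 to 6686 in CTNNB1_NFE2L2_MET, 1294 to 2249 in CTNNB1_MET, 5700 to 6433 in CTNNB1_NFE2L2 and 2137 to 3008 in NFE2L2_MET. Genes higher in each CTNNB1 model numbered 186 to 241. The lowest values came without CTNNB1_NFE2L2 replicate 2 for MET added (2259), CTNNB1_MET replicate 1 for that model against WT (1294) and NFE2L2_MET replicate 3 for that model against WT (2137), and the cause was not tested. With an estimated correlation 1 list test passed. Leaving out 1 library, tried for the lists after the data were seen, ended 23 of 134 list calls.

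The alternatives added after the data were seen moved more counts. Total-count scaling gave 6928 genes for CTNNB1 added and 5792 for the CTNNB1 models against NFE2L2_MET. The term for the unmapped share gave 2554 for CTNNB1 added, 576 for NFE2L2 added, 298, 540, 608 and 141 for CTNNB1_NFE2L2_MET, CTNNB1_MET, CTNNB1_NFE2L2 and NFE2L2_MET against WT, and 36 for the genes higher in each CTNNB1 model. The term itself called 0 genes, and since 91.1% of its variance lay between groups it widens the errors by construction.

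Of 1150 gene values, 670 were unchanged with the term for the unmapped share, 460 lost the call, 5 gained it and 15 changed sign. In CTNNB1_NFE2L2_MET against WT these were Car1 0.53, Cyp2d9 0.10, Mup9 1.74, Slc4a1 -2.73 and Socs3 -0.88. In CTNNB1_NFE2L2 against WT they were Ccl6 -0.44, Cxcl16 -0.32, Cyp2e1 0.43, Irf8 -0.13, Itgax -0.38 and Tapbp -0.54. In NFE2L2_MET against WT they were Cyp4a12a 0.0273, Mup7 0.25, Nags 0.0122 and S100a9 -0.23. Without WT replicate 2, Saa3 in NFE2L2_MET against WT turned from -2.63 to 2.09 (-3.20 without WT replicate 1), and that library held most Saa3 counts of its group. Leaving out 1 library was counted once for each gene value and each library of its contrast, where 7067 stayed the same, 623 lost the call, 85 gained it and 1 changed sign. DESeq2 weakened 12 and strengthened 36, RLE 3 and 2, and the fit without the 3 marked libraries 87 and 18.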

Other observations

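Of the tests weighed here, the new cartilage markers were set before their values were seen, and the tests on stellate cells and fibroblasts and on sex-biased, Y-linked and clock genes were chosen only after the results were seen.

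Cartilage genes such as Col2a1 and Acan were high in 2 of 3 WT libraries. Acan stood at 35.7, 35.8 and 10.4 CPM in WT. Markers not looked at before had a median of -1.42 over 13 genes in the models against WT, which is what cartilage cells in those WT samples would give. More stellate cells and fibroblasts in WT stays open. That list lay 0.95 above the cartilage median (-0.59 ± 0.34 against -1.54 ± 0.18), but its members went both ways with a standard deviation of 1.01, and Col1a1 and Lox followed the cartilage genes. The source of the cartilage RNA was not tested further.

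Female-biased liver genes rose as a list in CTNNB1_MET against WT, also with an estimated correlation (adjusted p = 0.0278). In NFE2L2_MET the list was called only at the preset correlation (adjusted p = 0.0102, and 0.231 with an estimated correlation), and its median of 0.93 ± 1.26 lay within its error of 0. Male-biased genes had medians of -2.53 ± 0.40 in CTNNB1_NFE2L2_MET, -0.75 ± 0.27 in CTNNB1_MET, -2.34 ± 0.88 in CTNNB1_NFE2L2 and -0.87 ± 0.51 in NFE2L2_MET, and no fall of this list passed with an estimated correlation. Female animals among the models are excluded, since the lowest median of 4 Y-linked genes was -0.74, and loss of the Y chromosome would leave almost no counts. Less hepatocyte RNA would lower both sets, and in CTNNB1_MET the female-biased median was 3.70 ± 1.03 (4.11 with 2 of 10 genes set at a floor of 3 counts in WT). The list was taken up because of this rise, so the sign of its median was known beforehand. Less hepatocyte RNA alone would not give the rise, but it could still lower the male-biased genes there. In the groups with lower male-biased genes the smallest gap between the sets was 1.80 ± 1.36, which cannot decide. A change in growth hormone signalling, which sets this sexual pattern, may underlie the median of 3.70, and pulsatility was not measured.

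Clock-controlled genes were compared without a list test between groups, and single libraries stood apart in them. Arntl stood at 3.02, 0.89 and 14.1 CPM in WT replicates 1, 2 and 3, and Dbp at 6.503, 37.3 and 37.2 CPM in those of CTNNB1_NFE2L2_MET. In CTNNB1_NFE2L2_MET the clock output genes had a median of -1.17 ± 0.29 and the genes of opposite phase -0.17 ± 0.57, a difference of -1.005. Harvest at another clock time would need opposite signs, and the second median lies within its error of 0, so this stays open for the group and for single libraries. The clock output genes lay only -0.27 from the hepatocyte list, so loss of liver identity could give the same value. The labels give no time of harvest, and the tests cannot separate these explanations.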
